A study of Sus scrofa with 8 samples.

How the data were processed

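The study compared total RNA from backfat of KNP and YS pigs, 4 samples per breed, by biotin labelling and hybridization to the Affymetrix GeneChip Porcine Genome Array, a 1-colour array, with extraction and labelling described only as the manufacturer's protocol. The table deposited by the authors held 1 intensity per probe set and array for 24123 probe sets. The deposited intensity was on a linear scale, and its mean over probe sets, trimmed by 2% at each end, was 500 on every array, while medians and the shapes of the distributions differed. This scaling was read from the values, and the algorithm that summarised probes into probe sets is not given in the sources used here. No detection calls came with the values. As a guide to background, the 95th percentile of 23 control probe sets with no target in pig RNA was taken on each array, and it ranged from 40.6 to 161 in signal. Array data carry no counts, so the precision of each value rests on the 4 arrays per breed. The labels give a sample size of 4 per breed, and do not say whether each sample came from a different animal. The SDs and p-values measure the spread between these samples, and stand for animals only if they did. Sex was not stated, and age was wholly tied to breed.

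The authors' scaling was kept, since trimmed means were equal. Values were transformed to log2(signal + 16), 124 control probe sets were left out, and the 25% of the other 23999 probe sets with the lowest mean over all 8 arrays were left out, which left 17999. Gene names came from the platform's annotation, in which 10069 probe sets had 1 gene symbol, 198 had several and 13732 had none. The annotation can be old: of 10099 single-gene entries 9989 were matched through the Entrez identifier to the RefSeq annotation of the pig assembly Sscrofa11.1, and 0 symbols changed. Probe sets have no positions in the sources used here, so no coordinates are given. Probe sets without a symbol were tested but not named, and each of the 6006 named genes was represented by its probe set with the highest mean.

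Breeds were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. The labels do not pair samples across breeds by replicate number, so the numbers were not used as pairs. As a block they were an alternative. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 29 lists with at least 5 genes, and again with an estimated correlation and with fry. The list value given as a shift is the mean difference of its genes minus that of all other genes. Similarity of arrays was tested by an exact permutation over the 35 splits of 8 arrays into 4 and 4. The test was tried on simulated data with the means and spreads of these probe sets, in which 200 of 17999 were changed: it made 4 false calls, and with no change at all it made 0 calls and gave an unadjusted p under 0.05 for 5.07%. Values were drawn independently, so variation that genes share across the real arrays was not simulated.

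The comparisons, the 32 gene lists, the filter, the thresholds and all alternatives but 1 were chosen before the data were examined. Genes were named by a rule fixed at the same time. It took up to 12 genes per direction past the threshold with no overlap between breeds, by size of difference, and, where fewer passed, genes in order of p up to 5 per direction. It added from each list up to 4 members past the threshold, or the 2 with the smallest p where none passed. As 0 genes passed, all named genes came from the order of p. The 5 per direction were taken only among genes with no overlap between breeds, so their lack of overlap is not a result. The lists covered lipid, energy and cholesterol metabolism, adipocyte regulators and secreted factors, insulin signalling, extracellular matrix, retinoid, steroid and xenobiotic metabolism, clock, stress, antigen presentation, interferon, cell cycle and ribosomal genes, trait genes, and markers of muscle, vessel, blood, immune, skin, nerve and fibroblast cells. Lists for skeletal muscle, skin, red blood cells and Y-linked genes served as checks on the samples.

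Alternatives were no filter, a filter of 50%, quantile normalization, median centring, pseudocounts of 1 and 64, a variance model with trend and robust fitting (statmod 1.5.0 was loaded with limma), array weights, a replicate block, the 3'/5' difference of the housekeeping controls as a covariate, each array left out in turn, an adjusted p of 0.10, a 2-fold minimum, the mean of a gene's probe sets, and Spearman's rho for the distance. The alternative without the 3 arrays of largest 3'/5' difference was chosen after seeing the data. The 3'/5' difference of an array was the mean, over the actin, GAPDH and elongation factor controls, of the log2 signal of the 3' minus that of the 5' probe sets, and the same was computed for 7 pairs of bacterial spike-in controls. Among the arrays kept without those 3, this difference was smaller on every KNP array than on every YS array.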

Results

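Gene expression was measured in backfat, the subcutaneous adipose tissue of the back, from 2 breeds of pig grown under the same conditions. The labels name the breeds KNP and YS; one of them gives YS as Yorkshire, and KNP is not spelled out. There were 4 KNP samples, taken at 7 months of age, and 4 YS samples, taken at 6 months, each on 1 Affymetrix GeneChip Porcine Genome Array. The arrays carried 24123 probe sets, and the median signal per array ranged from 158.2 in YS replicate 2 to 263 in YS replicate 4, after every array had been scaled to a trimmed mean of 500. The number of arrays, 4 per breed, limits the precision of every value, and breed and age could not be separated because all KNP samples were 1 month older. The labels do not say whether each sample came from a different animal. Log2 values are log2(signal + 16), and means are given with the SD over 4 arrays.

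The main comparison asked which transcripts differed in backfat between KNP and YS pigs. No single gene was separated from the rest by the test: of 17999 probe sets, 0 passed an adjusted p of 0.05 in limma, 0 passed 0.10, and the smallest adjusted p was 0.762. At an unadjusted p under 0.05 there were 511 probe sets, 268 higher and 243 lower in KNP, where 900 would be expected with no difference at all. Single arrays moved this count and its balance: 884 without YS replicate 4, of which 631 (71.4%) were higher in KNP, and 784 without KNP replicate 1, of which 294 (37.5%) were higher. With the 3'/5' signal difference of the housekeeping controls as a covariate there were 877, of which 307 (35.01%) were higher. The 4 KNP values lay wholly above the 4 YS values for 198 probe sets and wholly below for 154, together 1.96% of those tested, against 2.86% expected by chance. The difference between the breed means was at least 2-fold for 660 probe sets. The median absolute log2 difference of 0.24 was smaller than the median SE of such a difference, 0.37. The count of 0 held in each of 21 alternative settings. Of these, the 2-fold minimum could only give 0, and the adjusted p of 0.10 was a looser threshold on the main fit. Over the settings the smallest adjusted p reached 0.0596, when the variance was modelled with a trend and robustly. Values were also simulated with the same spread, drawn independently for each probe set and array. On these the test recovered 4% of 2-fold, 44% of 4-fold, 60% of 8-fold and 90% of 16-fold changes. Recovery on the real arrays, where genes vary together, can differ.

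The gene ranked first was TMEM158, a transmembrane protein induced by Ras signalling with the smallest p of all 17999 probe sets. Its log2 signal was 9.70 ± 0.34 in KNP and 7.64 ± 0.35 in YS (SD, n = 4), a 4.18-fold higher mean in KNP with a log2 difference of 2.06 ± 0.28 (SE), and its adjusted p was 0.762. Next in that direction, among genes with no overlap between breeds, was GATB, at 7.25 ± 0.24 against 5.30 ± 0.69. It encodes a subunit of the mitochondrial glutamyl-tRNA amidotransferase. ECE1, which processes endothelin, was at 7.23 ± 0.47 against 5.58 ± 0.51. The metallothionein MT3 was at 7.89 ± 0.33 against 5.94 ± 0.97, and MSTO1, a regulator of mitochondrial distribution, was at 7.01 ± 0.48 against 5.44 ± 0.62. For these 4 genes the YS signal lay near the background: GATB, MT3 and MSTO1 were each above the level of the no-target control probe sets on 1 YS array and ECE1 on 0. None of them passed the test.

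Among genes with lower signal in KNP and no overlap between breeds, the first by p were PRIM2, DECR1, USP18, PLPPR5 and C4BPA. None of these passed. PRIM2, a subunit of DNA primase, was at 6.72 ± 0.59 in KNP and 8.26 ± 0.37 in YS (SD, n = 4), above the no-target level on 2 KNP arrays. DECR1, the mitochondrial dienoyl-CoA reductase needed to oxidise unsaturated fatty acids, was at 9.55 ± 0.26 against 10.56 ± 0.20, a difference of -1.02 ± 0.24 (SE), and its mean in YS was 2.03-fold that in KNP. USP18, the protease that removes ISG15 from proteins and restrains interferon signalling, was at 9.57 ± 0.20 against 10.56 ± 0.26, a difference of -0.99 ± 0.24 (SE). C4BPA, which encodes the alpha chain of a complement inhibitor, was at 12 ± 0.29 against 13.18 ± 0.48, a difference of -1.18 ± 0.31 (SE). PLPPR5 was at 5.45 ± 0.95 against 7.20 ± 0.28 and lay above the no-target level on 0 KNP arrays. All 10 ranked genes were chosen among those with no overlap between the breeds, so their separation was set by the choice.

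**Figure D1:**
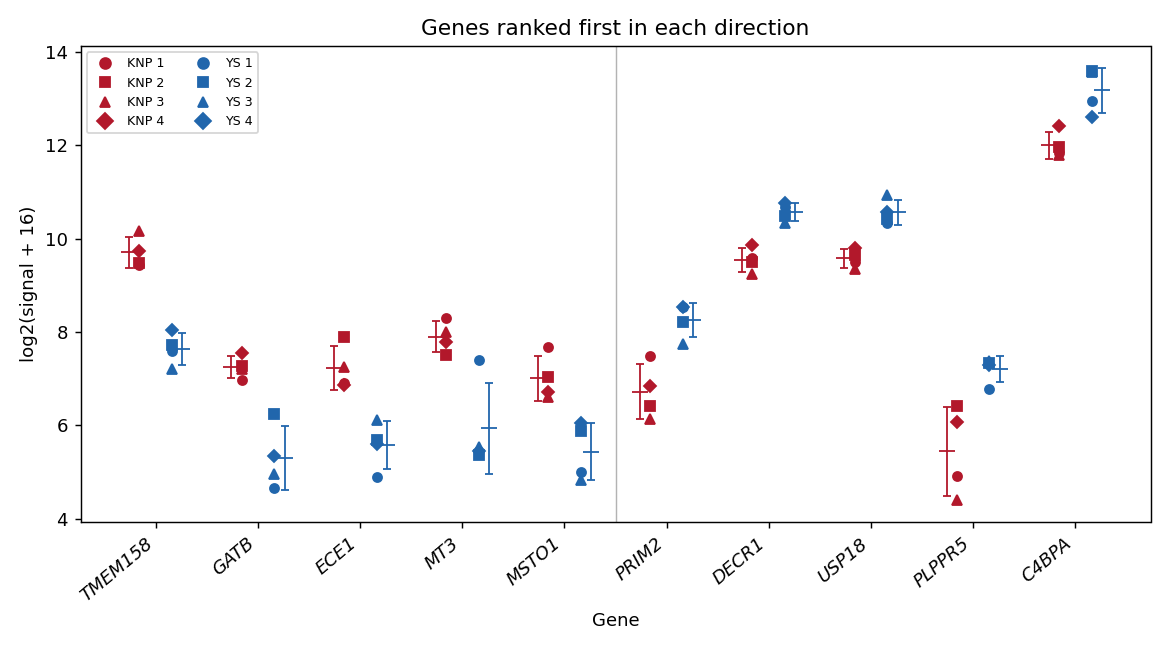
Log2(signal + 16) on the vertical axis for the 5 genes ranked first higher and the 5 ranked first lower in KNP, with KNP arrays in red, YS arrays in blue, 1 marker shape per replicate number and bars for the mean and SD of 4 arrays. The 10 genes were chosen among those with no overlap between the breeds. TMEM158 has means of 9.70 and 7.64, and none of the genes passed the test.

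Of 32 gene lists fixed before the data were examined, 29 had at least 5 measured genes and were tested with camera, and 7 passed an adjusted p of 0.05 with a preset correlation between genes of 0.01. Lists for the extracellular matrix, the interferon response, the cell cycle and antigen presentation were lower in KNP, and lists for skeletal muscle, cytosolic ribosomal proteins and the immediate early and heat shock response were higher. With the correlation estimated from the 8 arrays, 0 lists passed and 0 had an unadjusted p under 0.05; with fry, which asks whether the genes of a list move on balance one way, 0 passed and 1 had an unadjusted p under 0.05. No member of any list passed, over all probe sets or adjusted over the list alone. The count of 7 became 4 without KNP replicate 2, 3 without KNP replicate 3 and 4 without YS replicate 3.

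Extracellular matrix genes, which encode collagens, proteoglycans and the proteins that bind them, were lower in KNP for 33 of 41 members, with a median log2 difference of -0.26 (adjusted p = 0.000196; adjusted p = 0.704 with an estimated correlation). The elastic fibre glycoprotein MFAP5 was at 10.94 ± 0.16 in KNP and 12.13 ± 0.73 in YS (SD, n = 4), with every KNP array below every YS array. For TIMP3, an inhibitor of matrix metalloproteinases, the probe set used was at 7.90 ± 0.30 against 6.41 ± 1.06, and another TIMP3 probe set was at 6.76 ± 1.31 against 7.24 ± 0.79, with the opposite sign. Neither gene passed the test. The list's shift against the other genes was -0.28 in 8 arrays. Leaving out 1 array at a time kept it past the threshold with the preset correlation, but the shift ran from -0.17 without YS replicate 3 (adjusted p = 0.0384) and -0.19 without KNP replicate 1 (0.0256) to -0.45 without YS replicate 4 (6.03e-08). The list's medians per array were lowest on KNP replicate 1 and YS replicate 4, at -0.39 and -0.35 around the gene means, which were also among the 3 arrays with the largest 3'/5' signal difference. In the list of fibroblast and adipocyte progenitor markers, which also holds MFAP5, 13 of 20 genes were lower and the median was -0.17 (adjusted p = 0.2495, and 0.0168 without YS replicate 4; adjusted p = 0.760 with an estimated correlation). Its other named member, the collagen-binding proteoglycan lumican (LUM), was at 12.66 ± 0.63 against 13.44 ± 0.51.

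Genes of the interferon response were lower in KNP for 20 of 27 members, with a median difference of -0.36 (adjusted p = 0.00158; adjusted p = 0.704 with an estimated correlation). Besides USP18, the named member was OAS1, an antiviral oligoadenylate synthetase, at 8.23 ± 0.79 in KNP and 9.48 ± 0.85 in YS (SD, n = 4). The list's shift against the other genes was -0.28 in 8 arrays, -0.16 without KNP replicate 3 (adjusted p = 0.0808) and -0.12 without YS replicate 3 (0.236). It was -0.44 without YS replicate 1 (adjusted p = 2.19e-06) and -0.40 without KNP replicate 4 (4.86e-05). Without the 3 arrays with the largest 3'/5' difference the shift was also -0.28, though with 5 arrays the list did not pass (0.280). In the list for the major histocompatibility complex and antigen presentation 18 of 23 genes were lower, with a median of -0.32 (adjusted p = 0.0168; adjusted p = 0.742 with an estimated correlation). TAP1, a transporter of peptides for class I molecules, was at 9.60 ± 0.25 against 10.39 ± 0.55, and the class I gene SLA-8 was at 11.02 ± 0.36 against 11.72 ± 0.48. Its shift was -0.25 in 8 arrays and smaller without KNP replicate 1 (-0.05, adjusted p = 0.607), without YS replicate 3 (-0.09, 0.460), with array weights (-0.12, 0.383), with the 3'/5' covariate (-0.10, 0.274) and without the 3 arrays (-0.0075, 0.962). With the mean of each gene's probe sets it was -0.19 (0.0706). The list also did not pass without KNP replicate 3 (0.0808) or YS replicate 4 (0.0872), where the shift was -0.24 and -0.25. The shift was larger without KNP replicate 4 (-0.42, adjusted p = 0.00020) and without YS replicate 1 (-0.37, 0.00029). T and NK cell markers were lower for 10 of 15 genes, with a median of -0.27 (adjusted p = 0.0909; adjusted p = 0.742 with an estimated correlation). This list passed with median centring (adjusted p = 0.0343), with the replicate block (0.0399) and without KNP replicate 4 (0.000304), YS replicate 1 (0.0216) or YS replicate 2 (0.0166). Its shift was -0.35 in 8 arrays and 0.04 without the 3 arrays. The chemokine CCL5 was at 7.47 ± 1.27 against 9.16 ± 0.63 and the early activation marker CD69 at 6.20 ± 0.81 against 7.35 ± 0.79, above the no-target level on 1 KNP array.

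Cell cycle genes were lower in KNP for 15 of 19 members, with a median of -0.33 (adjusted p = 0.00225; adjusted p = 0.704 with an estimated correlation). Ribonucleotide reductase subunit RRM1 was at 9.97 ± 0.27 in KNP and 10.56 ± 0.22 in YS (SD, n = 4), and cyclin A2 (CCNA2) was at 5.40 ± 1.36 against 7.11 ± 0.41, above the no-target level on only 1 KNP array. The list's medians were highest on KNP replicate 1 (0.73) and YS replicate 4 (0.72), and its shift was -0.42 in 8 arrays. It did not pass without KNP replicate 3 (shift -0.29, adjusted p = 0.0808) or YS replicate 4 (-0.32, 0.0710), and its largest shift with 1 array left out was -0.58, without KNP replicate 1 (4.66e-05). Cytosolic ribosomal protein genes were higher in KNP for 52 of 57 members by a median of 0.15 (adjusted p = 0.00107; adjusted p = 0.759 with an estimated correlation). RPL38 was at 15.19 ± 0.22 against 14.84 ± 0.21 and RPL26 at 6.96 ± 0.56 against 6.08 ± 1.26. RPL26 lay above the no-target level on 2 KNP arrays and 1 YS array, and another probe set of RPL38 had the opposite sign, at 10.75 ± 0.37 against 11.38 ± 0.97. The list's shift was 0.15 in 8 arrays, and it did not pass with quantile normalization (shift 0.06, adjusted p = 0.233), without KNP replicate 2 (0.10, 0.146), without YS replicate 4 (0.10, 0.0661) or without the 3 arrays with the largest 3'/5' difference (0.04, 0.862). With 1 array left out, its largest shift was 0.22, without KNP replicate 4 (4.96e-06).

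Immediate early and heat shock genes, which are induced within minutes to hours of a stimulus or stress, were higher in KNP for 25 of 35 members, with a median of 0.09 (adjusted p = 0.0270; adjusted p = 0.704 with an estimated correlation). The nuclear receptor NR4A3 was at 9.85 ± 1.03 in KNP and 7.77 ± 0.50 in YS (SD, n = 4), a 4.21-fold higher mean with all KNP arrays above all YS arrays. The transcription factor ATF3 was at 10.23 ± 0.60 against 9.41 ± 0.40. Neither passed the test. The list was past the threshold without KNP replicate 1, YS replicate 1 or YS replicate 2, but not without any 1 of the others. Its shift was 0.24 in 8 arrays, 0.19 without KNP replicate 2 (adjusted p = 0.148), 0.17 without KNP replicate 3 (0.317) and 0.19 without YS replicate 3 (0.248). It stayed near the full value without KNP replicate 4 (0.23, adjusted p = 0.103) and YS replicate 4 (0.23, 0.0661), and it was 0.39 without KNP replicate 1 (0.000136). In the circadian clock list, 6 of 8 genes were lower in KNP with a median of -0.14 (adjusted p = 0.266). The clock-linked repressor BHLHE40 was at 6.05 ± 0.93 against 7.23 ± 0.13, above the no-target level on 2 KNP arrays, and ARNTL, which encodes the clock activator BMAL1, was at 8.02 ± 1.03 against 8.87 ± 0.44.

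Skeletal muscle genes were higher in KNP for 26 of 30 members, with a median of 0.98 (adjusted p = 8.44e-05; adjusted p = 0.704 with an estimated correlation), and KNP replicate 2 alone set this value. The list's median lay 3.10 above the gene means on that array and between -0.63 and 0.04 on the other 3 KNP arrays. Without KNP replicate 2 the shift of the list against the other genes was 0.0059 (adjusted p = 0.985). Beta-tropomyosin (TPM2), also found in smooth muscle, was at 10.70 ± 0.58 in KNP and 9.44 ± 0.35 in YS (SD, n = 4), with every KNP array above every YS array. Desmin (DES), the intermediate filament protein of muscle cells, was at 8.17 ± 0.58 against 6.68 ± 0.94, above the no-target level on 2 YS arrays. Smooth muscle and pericyte markers, which include DES, were higher for 11 of 14 genes with a median of 0.23 (adjusted p = 0.0972; adjusted p = 0.704 with an estimated correlation). This list passed with array weights (adjusted p = 0.0275), with the 3'/5' difference as a covariate (0.00559), without KNP replicate 1 (0.00257) and without the 3 arrays with the largest 3'/5' difference (0.00841). The pericyte marker RGS5 was at 10.02 ± 0.73 against 10.85 ± 0.35.

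**Figure D2:**
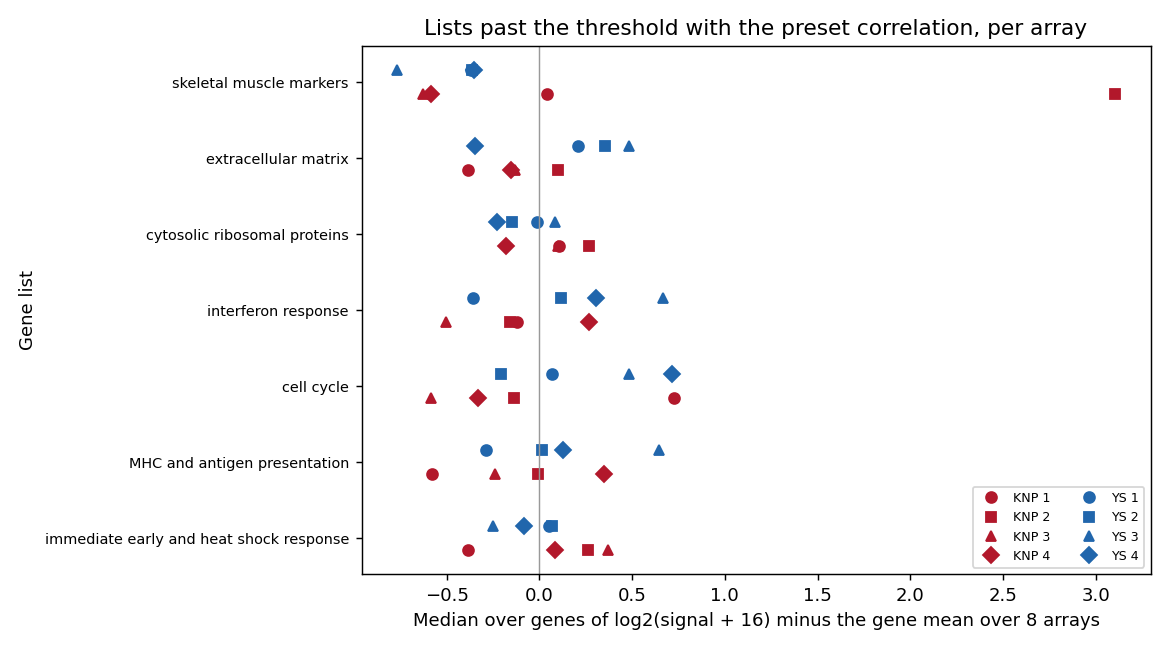
For each of the 7 gene lists past the threshold with the preset correlation, the horizontal axis gives the median over the list's genes of log2(signal + 16) minus the gene's mean over 8 arrays, 1 point per array, with KNP in red and YS in blue. KNP replicate 2 stands at 3.10 for skeletal muscle genes, and the breeds overlap in every list.

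The lists for the main metabolic functions of adipocytes did not pass. Fatty acid synthesis genes were lower in KNP for 14 of 22 members, with a median of -0.20 (adjusted p = 0.775). The elongase ELOVL1 was at 9.58 ± 0.28 in KNP and 8.99 ± 0.35 in YS (SD, n = 4), and the mitochondrial ketoacyl synthase OXSM was at 8.67 ± 0.17 against 9.05 ± 0.44. Triacylglycerol synthesis and lipid droplet genes were split evenly, 10 higher and 10 lower, with a median of 0.0069 and a mean of -0.02 (adjusted p = 0.969, towards higher). Their named members were the droplet proteins PLIN3, at 8.38 ± 0.47 against 7.91 ± 0.10, and PLIN2, at 9.70 ± 0.26 against 9.40 ± 0.30. Lipolysis genes had a median of -0.0064 and a mean of 0.0074 (8 of 15 lower, adjusted p = 0.969, towards lower). Monoacylglycerol lipase (MGLL) was at 12.88 ± 0.37 against 12.43 ± 0.47 and the adenosine receptor ADORA1 at 9.46 ± 0.34 against 9.86 ± 0.28. Fatty acid uptake genes had a median of 0.03 and a mean of -0.02 (10 of 17 higher, adjusted p = 0.969, towards higher). Within that list lipoprotein lipase (LPL), which frees fatty acids from circulating lipoproteins, was at 13.85 ± 0.34 against 14.35 ± 0.12 with all KNP arrays below all YS arrays, and the transporter SLC27A6 was at 8.20 ± 0.69 against 8.61 ± 0.16. Another SLC27A6 probe set had the opposite sign, at 6.94 ± 0.98 against 6.54 ± 0.93.

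Fatty acid oxidation genes had a median of -0.01 (14 of 27 lower, adjusted p = 0.746). DECR1 belonged to this list and had an adjusted p of 0.0598 over the list alone, and carnitine acetyltransferase (CRAT) was at 10.56 ± 0.46 in KNP and 9.83 ± 0.34 in YS (SD, n = 4). Oxidative phosphorylation genes were split 29 to 29 with a median of -0.0052 (adjusted p = 0.802). SDHC of complex II was at 9.98 ± 0.75 against 10.76 ± 1.01 and the ATP synthase subunit ATP5J at 11.03 ± 0.36 against 10.72 ± 0.19. The citrate cycle list was lower for 14 of 21 genes with a median of -0.07 (adjusted p = 0.162). Malate dehydrogenase MDH1 was at 13.39 ± 0.61 against 13.98 ± 0.50 and SUCLA2 at 10.87 ± 0.42 against 11.44 ± 0.20. Glycolysis genes were higher for 12 of 21 with a median of 0.07 (adjusted p = 0.969). The enolase ENO2 was at 7.14 ± 0.76 against 6.45 ± 0.48, above the no-target level on 2 YS arrays, and PFKP at 8.42 ± 0.42 against 8.83 ± 0.20. Cholesterol genes were split 9 to 9 with a median of 0.04 (adjusted p = 0.802). NPC1, which exports cholesterol from lysosomes, was at 11.17 ± 0.40 against 10.59 ± 0.56 and the sterol desaturase SC5D at 10.42 ± 1.08 against 11.11 ± 0.62. Without the 3 arrays with the largest 3'/5' difference, an alternative chosen after seeing the data, the lists for oxidative phosphorylation, the citrate cycle, fatty acid synthesis and glycolysis were past the threshold and lower in KNP, with adjusted p = 2.49e-14, 2.29e-06, 0.00841 and 0.0113. In the same order they had adjusted p = 0.494, 0.494, 0.4996 and 0.553 with an estimated correlation. The oxidative phosphorylation list also passed with array weights (adjusted p = 1.45e-06), without KNP replicate 1 (0.0489) and without YS replicate 4 (1.33e-06). The citrate cycle list passed with array weights (0.000183), with the 3'/5' covariate (0.0329), without KNP replicate 1 (0.00649) and without YS replicate 4 (0.00226). In 8 arrays they had adjusted p = 0.972 and 0.931 with an estimated correlation.

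Adipocyte transcription factors had a median of 0.09 (15 of 24 higher, adjusted p = 0.969). KLF9, a glucocorticoid-induced regulator of adipogenesis, was at 11.86 ± 0.34 in KNP and 12.59 ± 0.08 in YS (SD, n = 4) with all KNP arrays below all YS arrays. Another KLF9 probe set was at 6.27 ± 1.82 against 6.21 ± 0.72, with no such separation. The growth factor BMP4 was at 7.00 ± 1.08 against 7.61 ± 0.26. Adipokines had a median of 0.04 (13 of 21 higher, adjusted p = 0.30). The cytokine TNF was at 7.43 ± 0.49 against 6.21 ± 0.95, above the no-target level on 1 YS array, and adipsin (CFD) was at 12.63 ± 0.27 against 12.23 ± 0.33. Insulin and insulin-like growth factor signalling genes had a median of -0.06 (10 of 18 lower, adjusted p = 0.575). The binding protein IGFBP5 was at 9.16 ± 0.84 against 10.10 ± 0.92 and growth hormone (GH1) at 7.62 ± 0.96 against 6.70 ± 1.47. The list for retinoid, steroid and xenobiotic metabolism had a median of 0.0014 but a mean of -0.30 (15 of 31 lower, adjusted p = 0.30, towards lower). In it the cytochrome P450 gene CYP2A19 was at 8.54 ± 1.61 against 11.22 ± 1.11, a difference of -2.69 ± 0.82 (SE). CYP3A29 was at 6.25 ± 1.40 against 8.87 ± 0.96 but lay above the no-target level on 2 KNP arrays, and its difference ran from -3.07 with a pseudocount of 1 to -1.96 with 64. In both genes the breeds overlapped. Genes known for breed and growth traits in pigs had a median of -0.04 (11 of 21 lower, adjusted p = 0.775). PRKAG3, the AMP-activated kinase subunit known for its effect on muscle glycogen, was at 7.26 ± 0.62 against 5.65 ± 0.91 and the appetite peptide gene CARTPT at 6.14 ± 1.06 against 7.36 ± 0.72. They lay above the no-target level on 2 YS arrays and on 2 KNP arrays, respectively. None of these genes passed the test.

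Markers of the other cell types that backfat can hold did not pass either. Macrophage and myeloid markers had a median of -0.05 and a mean of 0.05 (14 of 26 lower, adjusted p = 0.861, towards higher). The myeloid protein S100A9 was at 8.26 ± 0.33 in KNP and 7.01 ± 1.20 in YS (SD, n = 4) and the chemokine receptor CCR1 at 8.66 ± 0.76 against 7.85 ± 0.20. S100A9 lay above the no-target level on 2 YS arrays. Endothelial markers had a median of -0.03 and a mean of 0.04 (10 of 18 lower, adjusted p = 0.969, towards lower). The water channel AQP1 was at 12.26 ± 0.63 against 11.52 ± 0.28 and the lymphatic marker LYVE1 at 7.13 ± 0.34 against 7.94 ± 0.77. Another LYVE1 probe set had the opposite sign, at 7.02 ± 0.56 against 6.77 ± 0.44. The macrophage and endothelial lists were past the threshold and higher in KNP without the 3 arrays with the largest 3'/5' difference (both adjusted p = 0.0472; adjusted p = 0.728 and 0.494 with an estimated correlation). Nerve and Schwann cell markers were higher in KNP for 5 of 7 genes with a median of 0.55 (adjusted p = 0.108, and 0.0432 without YS replicate 1; adjusted p = 0.704 with an estimated correlation). UCHL1 was at 8.84 ± 0.76 against 7.46 ± 1.24 and S100B at 10.10 ± 0.24 against 9.58 ± 0.31. Skin markers had a median of 0.07 (9 of 14 higher, adjusted p = 0.794). E-cadherin (CDH1) was at 8.13 ± 0.96 against 7.40 ± 0.61 and involucrin (IVL) at 6.94 ± 0.31 against 6.17 ± 1.33, above the no-target level on 1 YS array. The last lists had fewer than 5 measured genes and were not tested. Of 3 B cell and plasma cell markers 2 were lower in KNP. SDC1 was at 7.68 ± 0.64 against 7.97 ± 0.52, with 3 other probe sets of the opposite sign, and the immunoglobulin joining chain (JCHAIN) at 8.30 ± 0.90 against 7.97 ± 0.84. Of 4 red blood cell markers 3 were lower. The heme synthesis gene ALAS2 was at 7.38 ± 0.92 against 8.32 ± 0.44 and the globin gene HBM, higher in KNP, at 8.66 ± 0.41 against 7.65 ± 1.1. The 1 measured Y-linked gene, EIF1AY, was at 10.21 ± 0.18 against 10.51 ± 0.25. It lay above the no-target level on all 4 KNP and all 4 YS arrays, but 1 gene does not establish the sex of the samples.

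Arrays of the same breed were not more alike than arrays of different breeds. The mean distance (1 minus Pearson r across probe sets, which are not independent replicates) was 0.133 between breeds and 0.140 within breeds, a difference of -0.00706 (exact one-sided permutation p = 0.686, 24 of 35 splits as large). Pearson r ranged from 0.798 to 0.921 within KNP, from 0.808 to 0.927 within YS and from 0.800 to 0.929 between them. The first principal component held 34.1% of the variance and set KNP replicate 1 (-83.9) and YS replicate 4 (-90.8) apart from the other 6 arrays (8.84 to 43.4), and the second, with 17.3%, set KNP replicate 2 apart at 82.3. These 3 arrays also had the largest differences between the 3' and 5' probe sets of the pig housekeeping controls, at 8.54, 5.88 and 4.40 on the log2 scale for KNP replicate 1, KNP replicate 2 and YS replicate 4. The others lay between 2.12 and 3.17. KNP replicate 2 was also the array with the high skeletal muscle signal, so its place on the second component cannot be assigned to the 3'/5' difference. Leaving out the 3 arrays also leaves out that signal. The mean of this difference was 4.68 ± 3.11 in KNP and 3.31 ± 0.77 in YS (SD, n = 4; exact two-sided permutation p = 0.457). Without these 3 arrays the distance was 0.0111 larger between than within breeds (exact permutation p = 0.1, the smallest that 10 splits allow). In that setting 1516 probe sets, 8.42% of those tested, had an unadjusted p under 0.05, with 0 past the adjusted threshold in limma. Among the arrays kept there, the 3'/5' difference was smaller on every KNP array (2.20 and 2.12) than on every YS array (2.58, 3.17 and 3.10). That setting therefore cannot tell breed from the 3'/5' difference.

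**Figure D3:**
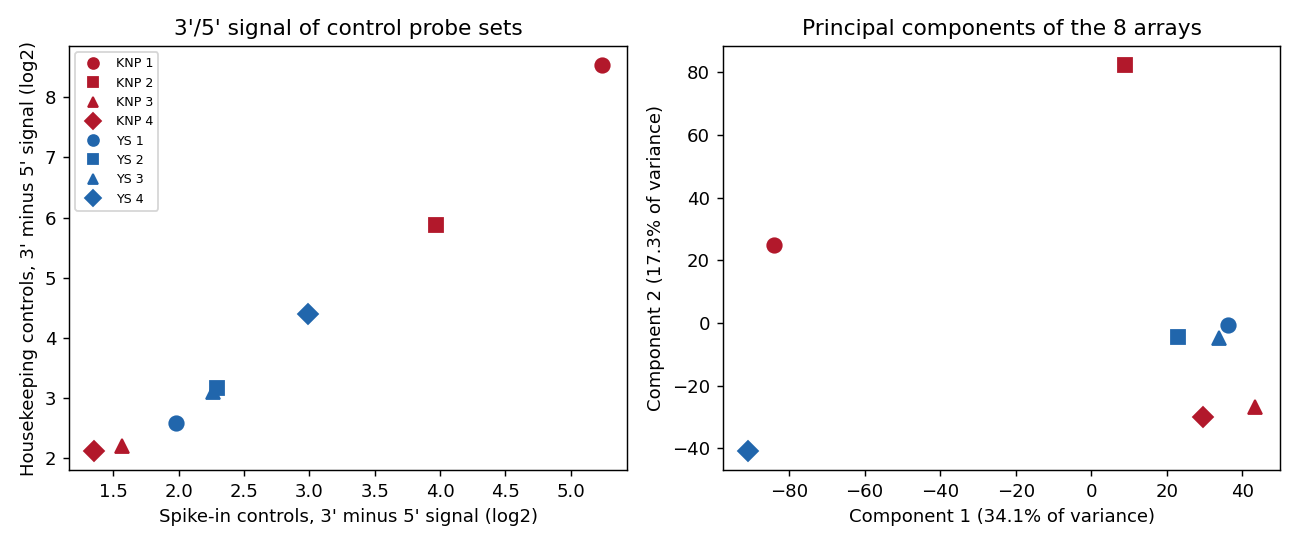
Left, the log2 difference between 3' and 5' probe sets for the bacterial spike-in controls (horizontal) and the pig housekeeping controls (vertical); right, the first (horizontal) and second (vertical) principal component scores of the tested probe sets, 1 point per array in both panels, KNP red and YS blue. KNP replicate 1, KNP replicate 2 and YS replicate 4 have the 3 largest housekeeping differences (8.54, 5.88 and 4.40). KNP replicate 1 and YS replicate 4 stand apart on the first component. KNP replicate 2, the array with the high skeletal muscle signal, stands apart on the second.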

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

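The tests of the muscle signal, of the 3'/5' differences, of the matrix list other than its count of splits, and the count of splits for the 0 probe sets were chosen after the results were seen.

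Skeletal muscle genes stood high on 1 array, KNP replicate 2. Of 30 measured muscle genes, 20 (66.7%) lay at least 2-fold above the highest of the other 7 arrays, against 32 (0.533%) of all 6006 genes. Among the most abundant on this array, chosen after their values were seen, were the fast-fibre genes TNNC2, MYL1 and MYLPF, at log2 signals of 13.86, 13.62 and 13.47, with the creatine kinase gene CKM at 13.55. These values may reflect skeletal muscle tissue in the sample, while a sample of muscle under an adipose label is argued against by 41 lipid droplet and adipokine genes, whose median on this array was 0.12 above the mean of the other arrays (quartiles -0.27 and 0.48). A breed difference is argued against as well, since the muscle genes' median difference between the other 3 KNP arrays and YS was -0.021 (quartiles -0.55 and 0.36).

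The 3'/5' difference of the housekeeping controls ranged over 6.42 log2 units between arrays. Breakdown of RNA in the tissue alone is argued against by the bacterial spike-in controls, which carry no tissue RNA and whose own 3'/5' difference ranged over 3.88. Across the 8 arrays both differences moved together (Pearson r = 0.994, permutation p = 2.48e-05; Spearman rho = 1, permutation p = 4.96e-05; 1 relation was computed, so adjusted values are equal), and r was 0.981 without the 2 farthest arrays, KNP replicates 1 and 2. Short products of the labelling reaction are a candidate explanation, as spike-ins of this kind are usually added before labelling, a step the labels do not describe. A difference between breeds stays open (exact permutation p = 0.457), since KNP held both the highest and the lowest values.

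Extracellular matrix genes were lower in KNP. Whether the 3 arrays with the largest 3'/5' difference are the source was not decided. Without them the median was -0.38, against -0.26 in all 8 arrays, and 34 of 41 genes were lower. The list passed with the preset correlation (adjusted p = 2.29e-06) but not with an estimated correlation (adjusted p = 0.494). The latter cannot decide the question, since the list did not pass it in 8 arrays either. The arrays kept also still differed by breed in the 3'/5' difference. Genes of this list vary together between arrays (estimated correlation 0.180), and counting them as independent may account for the call, since its adjusted p was 0.704 with that correlation. Chance could not be excluded: 8 of the 35 splits of the arrays, the real one included, gave a shift as large as the real -0.28, and the highest other was -0.53. Each of the others set KNP replicate 1 and YS replicate 4 on the same side. These arrays had the lowest list medians (-0.39 and -0.35), so the large shifts also reflect a structure of the samples. A difference that goes with breed or age remains open and untested.

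For the real count of 0 probe sets at an adjusted p under 0.05 in limma, the splits say nothing about chance: any split gives at least 0, so 35 of 35 was fixed in advance, and the highest other was 0. Chance could not be excluded for the other counts. As many as the real 511 at an unadjusted p under 0.05 came from 25 splits, the real one included. The highest other was 1992, in the split that set KNP replicates 1 and 2 with YS replicates 2 and 4. That split calls several times the real count and holds the 3 arrays with the largest 3'/5' difference on one side, which points to a structure of the samples. As many as the real 7 gene lists came from 16 splits, the real one included, with 13 as the highest other.

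Each of 202 groups examined held the 4 values of 1 measure in 1 breed. In 10 of them, 1 value stood apart from the other 3, where chance gives about 1 in 20 groups. The count is thus near the chance rate. That rate may also not hold for genes that were named by their p. The flags below are therefore descriptions and not findings. The rule did not flag the skeletal muscle list on KNP replicate 2, at 3.10 around the gene means. The median signal was high at 224 on KNP replicate 1 and at 263 on YS replicate 4, against means of 169 and 161 for the other 3. The fatty acid oxidation list lay low on YS replicate 4, at -0.30 around the gene means, and the skeletal muscle list lay low on YS replicate 3, at -0.76. On YS replicate 1, MT3 was high at a log2 signal of 7.40, and PLPPR5 (6.79), OXSM (8.39) and SLC27A6 (8.38) were low. RRM1 was low on KNP replicate 3, at 9.56, and ALAS2 was low on KNP replicate 2, at 6.02.

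Of 21 pig control probe sets outside the tests, 3 were at least 4-fold above the highest YS array on an array of KNP. All 3 were on KNP replicate 2, the array with the high skeletal muscle signal. The 3' and middle probe sets of a pig actin control were at signals of 20349 and 3973, against 560 and 223 at most in YS. The middle probe set of a control named for the CTLA4 receptor was at 71.1 against 17.6. The last value lay below the no-target level of that array, 115, so it compares signals at background.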

How the results depend on the processing

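The alternative without the 3 arrays of largest 3'/5' difference was chosen after the data were seen, and all others before. The count of 0 probe sets past the adjusted threshold held in limma under all 21 alternatives, the replicate block included. Among these, the adjusted p of 0.10 was a looser threshold on the main fit, and the 2-fold minimum could only give 0. The number at an unadjusted p under 0.05 ran from 423 without YS replicate 3 to 1516 without those 3 arrays (main value 511; replicate block 509, array weights 975, 3'/5' covariate 877, without YS replicate 4 884, without KNP replicate 1 784). The 7 gene lists became 0 with an estimated correlation and 0 with fry, and 3 to 9 when each array was left out, with 3 without KNP replicate 3 and 4 each without KNP replicate 2 and YS replicate 3. The shift of the skeletal muscle list ran from 0.0059 without KNP replicate 2 to 1.27 without KNP replicate 4, because KNP replicate 2 carries the muscle signal. Without the 3 arrays the shifts were -0.044 for skeletal muscle and -0.29 for glycolysis, opposite to those in 8 arrays. That of endothelial markers was 0.30, against 0.04 in 8 arrays, where the test's direction was lower. The cause was not tested. Otherwise, over the lists and alternatives, 509 values kept direction and side of the threshold, 66 changed the test's direction with neither value past the threshold, 22 passed in place of not passing and 36 no longer passed. Of the values for named genes, 1289 kept direction and 4 changed sign, none past the threshold. The similarity difference ran from -0.0117 without YS replicate 3 to 0.0111 without the 3 arrays. Scaling moved the median difference of all genes by under 0.1 on the log2 scale. Signal near background limits the comparison for weak genes, since the no-target level reached 161 on YS replicate 4.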

Other observations

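The lists in this part were fixed before the data were examined, and the setting with 5 arrays was chosen after they were seen.

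With KNP replicates 3 and 4 and YS replicates 1, 2 and 3 alone, the arrays with the smallest 3'/5' differences, 10 gene lists passed with the preset correlation. The 3'/5' difference of the housekeeping controls still separated the breeds in these arrays. It was 2.20 and 2.12 in KNP, against 2.58, 3.17 and 3.10 in YS. Breed and 3'/5' difference therefore cannot be told apart in this setting. Oxidative phosphorylation genes had a median difference of -0.52 between KNP and YS, citrate cycle genes -0.44, glycolysis genes -0.34 and fatty acid synthesis genes -0.58, all lower in KNP. In the same setting smooth muscle and pericyte markers had a median of 0.43 (adjusted p = 0.00841), macrophage and myeloid markers 0.44 (adjusted p = 0.0472) and endothelial markers 0.27 (adjusted p = 0.0472), all higher in KNP. With an estimated correlation their adjusted p were 0.494, 0.728 and 0.494, and those of the metabolic lists ran from 0.494 to 0.553. Over all alternatives run, the adjusted p of the oxidative phosphorylation list ranged from 2.49e-14 to 0.995, that of the macrophage list from 0.0472 to 0.995, and that of the smooth muscle list from 0.00257 to 0.865.

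The oxidative phosphorylation list shows how single arrays weigh on this. Its median around the gene means was 0.34, 0.10, -0.26 and -0.27 on KNP replicates 1 to 4, and 0.44, 0.17, 0.21 and -0.78 on YS replicates 1 to 4. In 8 arrays its median difference was -0.0052, without YS replicate 4 its adjusted p was 1.33e-06, and without KNP replicate 1 it was 0.0489, all with the preset correlation. In 8 arrays its estimated correlation was 0.655, with adjusted p = 0.972 with an estimated correlation. Immediate early and heat shock genes were higher in KNP in the 5 arrays as in all 8, with medians of 0.30 and 0.09, and cell cycle genes were lower in both, with -0.53 and -0.33. Neither list passed with the correlation estimated: both had adjusted p = 0.494 with an estimated correlation in the 5 arrays and 0.704 in all 8. No cause was tested for these values, and 2 against 3 arrays leave only 10 splits.

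Arrays of KNP and YS with the same replicate number did not stand out as alike, which does not exclude pairing. Removal of the breed means makes the remaining values balance within each breed, so correlations of both signs arise. After removal of the breed means, the correlation across probe sets, which are not independent replicates, between KNP and YS arrays with the same number was -0.17, 0.02, 0.13 and -0.19 for numbers 1 to 4. The highest value, 0.40, was between KNP replicate 1 and YS replicate 4.

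The control probe set for the hybridization spike cre had its highest signals on YS replicate 4 (157828), KNP replicate 1 (134943) and KNP replicate 2 (109457), against 60807 to 90235 on the other 5 arrays. These are the arrays with the largest 3'/5' differences of the housekeeping controls.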
